A study of Homo sapiens with 9 samples.

How the data were processed

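RNA bound to tagged ribosomes was sequenced from 9 xenograft tumours, 5 grown from MDA-MB-231 cells injected with an equal number of human bone marrow MSC and 4 without them. Per the labels' protocols, polysomes were pulled down with anti-GFP beads from the lysate of whole tumours, and libraries were made with a TruSeq RNA kit. The deposited files hold whole-number counts per gene symbol, not normalized. The submitters' processing notes name CASAVA 1.8.1, TopHat 1.4.0 and HTSeq, and the genome build hg19. The gene annotation, the HTSeq version and settings, and whether strand was used are not given in the sources used here. Reads of overlapping genes and of near-identical paralogs can therefore be lost or misassigned. Whether reads of mouse cells were removed is not given either, so mouse RNA in conserved genes can add to human counts.

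Each table had 21619 genes plus lines for reads assigned to no gene, which took 10.2 to 12.1% of all counts in a library and were left out of library sizes and tests. The tables held no mitochondrially encoded genes, so their share was not analysed here. Gene totals were 24616792 to 65275226 counts per library. No 2 libraries agreed within sampling noise: the smallest chi-square per degree of freedom of a pair within a group was 23.9. The groups share no replicate numbers and the labels name no batch, so no pairing or batch term was used.

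Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr, TMM factors, glmQLFit with robust=TRUE, and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 CPM used a prior count of 2, and marker list means a pseudocount of 0.05 CPM over all genes of the list. SE of a log2 change was its size divided by the square root of the F statistic. 28 gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 (limma 3.58.1), adjusted over the 26 lists with at least 5 tested genes. None of the 16 lists past the threshold passed with an estimated correlation (smallest adjusted p 0.206), and 16 lists passed by fry, which tests a list without comparing it with other genes. Shares of counts and marker means were compared by exact two-sided permutation.

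Genes named in the text followed a rule set before the data were examined: the 12 largest rises and falls among called genes with a mean of at least 20 counts, up to 4 genes of smallest p in each list that passed or held a called gene, and RPL10A, CXCL12, CXCR4, IGF1 and IGF1R. Other named genes were chosen after their values were seen. Some genes that the rule takes are not reported here.

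GC content, transcript length and predicted proteins came from GENCODE release 29, matched by symbol to 95.7% of tested genes. A hydrophobic stretch was a 19-residue window with a mean Kyte-Doolittle value of at least 1.6, or an 11-residue window of at least 2.0 in the first 35 residues. For the GC correction, splines with 4 degrees of freedom on GC content and on log length were fitted to each library's deviation from the gene means and used as offsets. A true difference between the groups that follows GC content or length would be removed in part by this correction.

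The test was tried on simulated counts for this comparison, with the means, library sizes and dispersions of these genes and 13240 genes kept by the filter. It called 28 of 66 genes changed 1.5-fold, 52 of 65 changed 2-fold and 58 of 63 changed 4-fold, and 7 of 13046 unchanged genes, so many 1.5-fold changes are missed at this depth and group size. Camera called the 1 list raised 1.5-fold and 0 of 24 others. The simulated genes were drawn independently of one another, so this does not test camera's p-values for correlated genes. In the data the estimated correlation was 0.39 in the mitosis list and 0.53 in the hypoxia list. A simulated GC trend in 1 group gave 1939 calls without the correction and 0 with it. That trend followed the same GC values that the correction fits, so it does not show how much of a real bias is removed.

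Alternatives were DESeq2 size factors, library size only, upper-quartile factors, no filter, a filter of 5 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, robust=FALSE, an adjusted p threshold of 0.10, thinning to the smallest library, and leaving out each library. The GC correction, the fit without tumours 15 and 12 together, and an estimated correlation for the ribosomal protein list without tumour 15 and for oxidative phosphorylation without tumours 1, 6 or 7 were added after seeing the data.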

Results

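To investigate how mesenchymal stem cells in a tumour relate to gene expression of the cancer cells, the data compare human breast cancer cells grown in mice with and without added human bone marrow mesenchymal stem cells (MSC). The cancer cells were MDA-MB-231, an established triple-negative breast cancer line, carrying a ribosomal protein L10a fused to a green fluorescent protein. Polysomes with this tag were pulled down from whole tumours with an antibody to the fluorescent protein (translating ribosome affinity purification), so that the RNA sequenced was the polysome-associated RNA of the tagged cells, plus any carry-over. Tumours were taken 3 weeks after injection into the mammary fat pad, from 5 mice with MSC and 4 mice without, each tumour from its own mouse. The tables held counts for 21619 genes. Gene counts per library ran from 29749909 to 50639082 with MSC and from 24616792 to 65275226 without. No library of total tumour RNA was used here, so a change can come from RNA abundance or from ribosome association. Means ± SD below are in CPM, the counts scaled to a common library size, over n = 5 tumours with MSC and n = 4 without, and log2 fold changes are with MSC minus without, ± SE.

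Tumours grown with MSC differed from those without at many genes, mostly by modest amounts. As lists in camera with its preset correlation, hypoxia genes, endoplasmic reticulum chaperones and targets of TGF-beta were higher with MSC, while genes of mitosis, S phase and the interferon response were lower. None of these 6 lists passed with an estimated correlation (adjusted p = 0.206 to 0.244), and in 5 of them most genes did not pass singly. Of 13458 genes tested, 563 were higher and 484 lower with MSC (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 67 rose and 22 fell by a factor of 2 or more. A fold under 1.5 was found for 279 of the higher and 369 of the lower genes. The counts depended on single libraries: they were 151 higher and 94 lower without tumour 12 without MSC, 175 and 138 without tumour 9 without MSC, 260 and 191 without tumour 1 with MSC, 285 and 191 without tumour 10 with MSC, and 985 and 863 without tumour 13 without MSC. Without tumours 6 or 11, 350 and 390 genes were higher and 332 and 299 lower, and without tumour 15 with MSC 301 were lower.

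The largest rises by the fixed rule were of low-abundance genes. FLT1, the receptor VEGFR1, went from 0.329 ± 0.270 to 2.30 ± 0.553 CPM (log2 2.72 ± 0.50, edgeR adjusted p = 0.00483), and CRYAB, a small heat shock protein, from 0.518 ± 0.114 to 3.17 ± 2.10 CPM (log2 2.59 ± 0.46, edgeR adjusted p = 0.00403). Both kept their calls when any 1 library was left out, but limma-voom with quality weights ended that of CRYAB (adjusted p = 0.0864). The long noncoding RNA UCA1 had a log2 change of 3.26 ± 0.75, which was 2.02 at the lowest when 1 library was left out. Its call was lost without tumour 1 with MSC or tumours 9, 11 or 12 without (edgeR adjusted p up to 0.147). The cholesterol exporter ABCA1 rose by 2.81 ± 0.65, the basement membrane proteoglycan HSPG2 by 1.83 ± 0.41 and the collagen chain COL1A2 by 2.41 ± 0.51. COL1A2 was 8.45 CPM in tumour 15, which stood apart for fibroblast markers (below), and at most 2.64 in the others, and its log2 change was 1.61 without that tumour. The calls of ABCA1 and HSPG2 were lost without tumour 9 without MSC (edgeR adjusted p = 0.0510 and 0.0563), and that of COL1A2 without tumour 12 (0.0765). The nuclear receptor NR4A1 (log2 2.25 ± 0.57), the neuronal activity gene ARC (2.35 ± 0.71) and the transcription factor NFATC2 (2.31 ± 0.70) passed with edgeR adjusted p = 0.0443, 0.0454 and 0.0471. All 3 were lost in at least 5 of the 9 fits that left out 1 library. PSG4 (2.39 ± 0.69) and PSG5 (2.66 ± 0.79) are close copies of one another, and GCOM1 (2.29 ± 0.56) overlaps other genes, so their counts are uncertain. Leaving out 1 library ended the call of PSG5 in all 9 fits, of PSG4 in 7 and of GCOM1 in 2. Of the 12 rises named here limma-voom with quality weights kept FLT1, ABCA1 and NR4A1 and ended the other 9. ARC and NFATC2 were also lost with library size only, with thinning and after the GC correction described below, and NFATC2 with robust=FALSE. NR4A1 was lost with library size only and with no filter. Leaving out tumours 15 and 12 together ended the calls of UCA1, HSPG2, PSG4, PSG5, ARC and NFATC2.

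Among the largest falls were 2 aldo-keto reductases of steroid and aldehyde metabolism. AKR1C3 went from 21.9 ± 0.944 to 10.05 ± 0.811 CPM (log2 -1.12 ± 0.13, edgeR adjusted p = 0.000228) and AKR1C1 from 11.7 ± 3.06 to 3.63 ± 0.815 CPM (log2 -1.68 ± 0.21, edgeR adjusted p = 0.000232). AKR1C1 has a near-identical paralog, AKR1C2, and AKR1C3 is related to both, so reads can be shared or misassigned. APOBEC3G, a cytidine deaminase that restricts retroviruses, went from 16.2 ± 2.07 to 6.62 ± 1.11 CPM (log2 -1.29 ± 0.16, edgeR adjusted p = 0.000232), and MDFI, an inhibitor of myogenic transcription factors, from 18.6 ± 3.24 to 7.92 ± 1.96 CPM (log2 -1.23 ± 0.18). SHROOM2 (-1.28 ± 0.25) and the calcium sensor VSNL1 (-1.20 ± 0.24) also fell, and these 6 calls held when any 1 library was left out, though that of VSNL1 was lost without tumours 15 and 12 together. KLRC2 (-1.46 ± 0.30), which has close paralogs, NHLRC1 (-1.40 ± 0.39), SALL2 (-1.31 ± 0.34), TMCO2 (-1.11 ± 0.29), the protease inhibitor SERPINA1 (-1.10 ± 0.28) and NME5 (-1.92 ± 0.57) each lost the call in at least 1 such fit. NHLRC1 and NME5 lost it in 8 of the 9, and the change of NME5 was -1.28 without tumour 12. The GC correction ended the calls of TMCO2 and NME5, and NME5 was lost with library size only and limma-voom as well. Without tumours 15 and 12 together NHLRC1, TMCO2 and NME5 were lost.

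**Figure D1:**
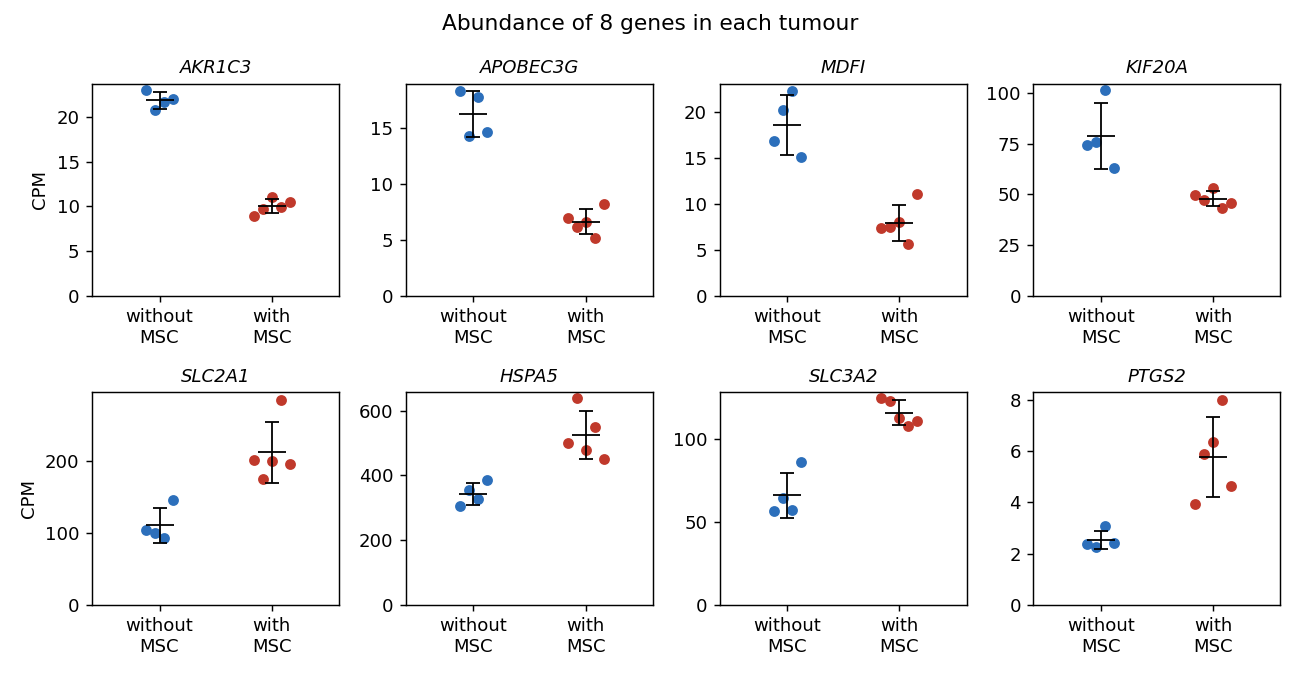
CPM in each tumour for 8 named genes, without and with MSC; dots are tumours (n = 4 and n = 5), bars the mean ± SD, and each panel has its own linear axis from 0. AKR1C3 was 21.9 ± 0.944 CPM without MSC and 10.05 ± 0.811 CPM with MSC.

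Genes of cell division were lower with MSC. In the list of G2 and mitosis genes, 17 of 36 tested genes fell and none rose, 27 when adjusted over the list alone, and all 36 had a negative log2 change (median -0.39, camera adjusted p = 2.33e-16, adjusted p = 0.206 with an estimated correlation). The kinesin KIF20A went from 78.7 ± 16.3 to 47.8 ± 3.77 CPM (log2 -0.72 ± 0.12, edgeR adjusted p = 0.00329), with smaller falls of the cyclin CCNA2 (-0.56 ± 0.12), the spindle checkpoint gene MAD2L1 (-0.54 ± 0.11) and the centromeric histone CENPA (-0.53 ± 0.12). Of the S phase genes, 7 of 37 fell and none rose, or 13 lower and 2 higher adjusted over the list alone (median -0.22, camera adjusted p = 5.70e-05, adjusted p = 0.244 with an estimated correlation). They included the ribonucleotide reductase subunit RRM1 (-0.53 ± 0.13), PCNA (-0.44 ± 0.12), MCM6 (-0.45 ± 0.12) and DTL (-0.45 ± 0.13). In edgeR 1 mitosis gene and no S phase gene passed without tumours 15 and 12 together, with medians of -0.32 and -0.17. Leaving out single tumours, the mitosis count was 10 (tumour 1), 7 (tumour 10), 5 (tumour 9) and 4 (tumour 12). The S phase count was 0 without tumours 1, 10 or 12, 1 without 9, 2 without 11, 3 without 6 or 15, and 11 without 13. PCNA, MCM6 and DTL lost their calls after the GC correction, and DTL also with library size only and with limma-voom. The change of DTL was -0.29 without tumour 12.

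Genes of hypoxia and of the endoplasmic reticulum were higher with MSC. In the hypoxia list 11 of 28 tested genes rose, 17 adjusted over the list alone, and all 28 had a positive change (median 0.58, camera adjusted p = 6.15e-13, adjusted p = 0.206 with an estimated correlation). The glucose transporter SLC2A1 went from 110.3 ± 24.3 to 211.7 ± 42.5 CPM (log2 0.94 ± 0.15, edgeR adjusted p = 0.00183). The collagen prolyl hydroxylase P4HA2 rose by 0.96 ± 0.15, the collagen crosslinking enzyme LOX by 0.87 ± 0.15 and hexokinase HK2 by 0.61 ± 0.13. Of the ER chaperones, 12 of 22 rose, 15 adjusted over the list alone, and all 22 had a positive change (median 0.38, camera adjusted p = 1.64e-11, adjusted p = 0.206 with an estimated correlation). HSPA5, the major chaperone of this compartment, went from 343.1 ± 34.5 to 523.8 ± 74.6 CPM (log2 0.61 ± 0.12, edgeR adjusted p = 0.00641), and HYOU1 (0.68 ± 0.13), CRELD1 (0.80 ± 0.15) and DNAJB9 (0.77 ± 0.15) rose as well. Of the ATF4 and amino acid stress genes 5 of 29 rose, also 5 adjusted over the list alone (median 0.26, camera adjusted p = 6.25e-05, adjusted p = 0.206 with an estimated correlation). These included the amino acid transporter subunits SLC3A2 (0.81 ± 0.12) and SLC7A5 (0.85 ± 0.16), the stress gene DDIT4 (0.88 ± 0.21) and the transporter SLC7A1 (0.51 ± 0.14). Without tumours 15 and 12 together, 9 hypoxia genes, 6 ER chaperones and 4 ATF4 genes passed in edgeR. The hypoxia count was 6, 7 and 5 without tumours 9, 11 and 12. For ER chaperones it was 7 without tumours 1 or 6 and 5 without 9, 10 or 12, and for ATF4 genes 3 without tumour 1 and 2 without 9, 10, 11 or 12. SLC7A1 lost its call in 6 of the 9 fits without 1 library, with library size only, with limma-voom and after the GC correction, and DDIT4 in 4 of the 9 and with no filter.

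**Figure D2:**
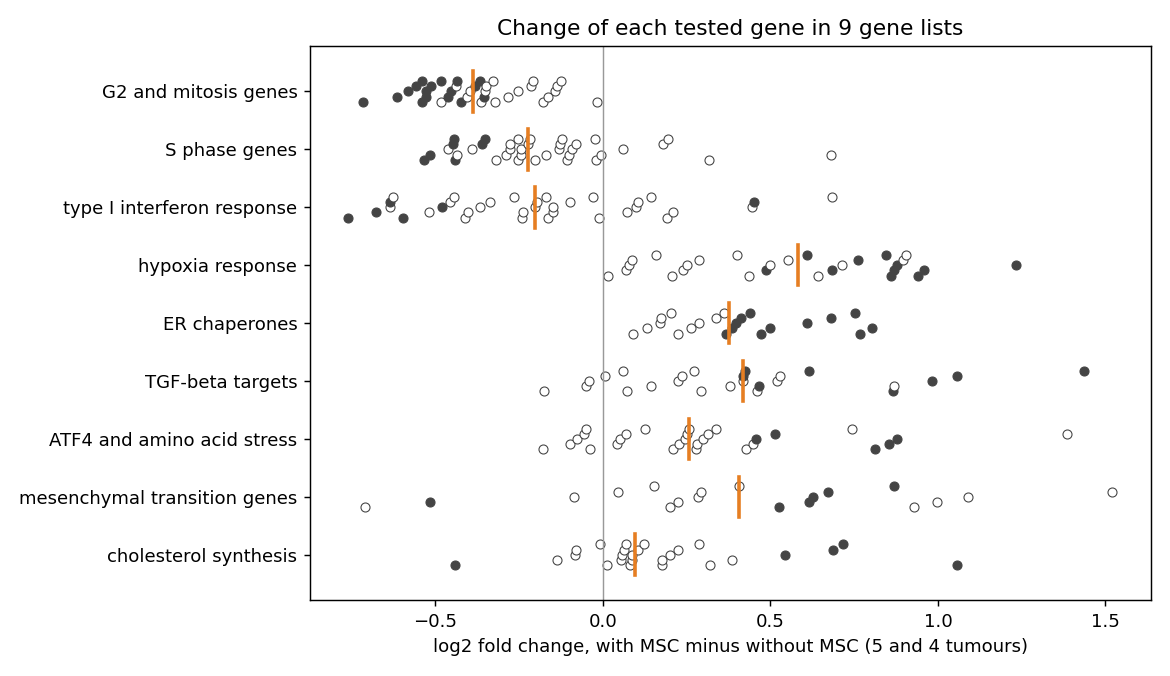
Log2 fold change (with MSC minus without, 5 and 4 tumours) of every tested gene in 9 fixed lists; filled dots passed the adjusted p threshold of 0.05 in edgeR, open dots did not, and the orange line is the list's median. All 36 G2 and mitosis genes lie below 0, and all 28 hypoxia genes and 22 ER chaperones lie above it.

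Lists of TGF-beta targets and of mesenchymal, epithelial and integrin genes were compared next. Of the TGF-beta targets 8 of 25 rose and none fell, 12 adjusted over the list alone (median 0.42, camera adjusted p = 4.19e-07, adjusted p = 0.206 with an estimated correlation). The basement membrane collagens COL4A1 (0.98 ± 0.19) and COL4A2 (0.87 ± 0.16) rose, COL4A2 from 28.8 ± 7.20 to 52.5 ± 9.94 CPM (edgeR adjusted p = 0.00559), as did HMOX1 (1.06 ± 0.23). Of the mesenchymal transition genes 5 of 19 rose and 1 fell, 7 and 2 adjusted over the list alone (median 0.41, camera adjusted p = 0.000582, adjusted p = 0.244 with an estimated correlation). LOX is in this list too, with the integrin ITGA5 (0.63 ± 0.14) and the receptor kinase AXL (0.53 ± 0.12). The epithelial list also moved up, with 4 of 14 genes higher, 7 adjusted over the list alone (median 0.34, camera adjusted p = 0.00109, adjusted p = 0.261 with an estimated correlation). Its named members were the tight junction gene CLDN7 (0.68 ± 0.12) and the keratins KRT14 (1.59 ± 0.41), KRT8 (0.46 ± 0.13) and KRT7 (0.47 ± 0.14). Of the integrin and focal adhesion genes 6 of 25 rose, 7 adjusted over the list alone (median 0.19, camera adjusted p = 0.00138, adjusted p = 0.335 with an estimated correlation). ITGA3 (0.58 ± 0.14), ITGB4 (0.72 ± 0.17) and ITGB3 (0.81 ± 0.22) were among them. Without tumours 15 and 12 together, 6, 2, 1 and 0 genes of these 4 lists rose in edgeR. With tumour 9 alone left out the counts were 4, 2, 1 and 0, and with tumour 12 alone also 4, 2, 1 and 0. Without tumour 1, 5 TGF-beta targets and 1 epithelial gene rose, and 2 epithelial genes rose without tumours 6 or 7. For integrins the count was 3 without tumours 7, 11 or 15 and 2 without 10. Tumour 15, set apart by fibroblast and MSC markers (mean log2 CPM 2.40 against at most 0.804, below), was also the highest of the 9 for smooth muscle markers (-0.0860 against at most -0.566), mesenchymal genes (5.04 against at most 4.81), TGF-beta targets (5.87 against at most 5.68) and, by little, integrins (4.68 against at most 4.67). By median, integrins went to 0.11 without tumour 15 and mesenchymal genes to 0.25 without tumour 12. After the GC correction 5 TGF-beta targets rose and the median of that list was 0.25, and without tumours 15 and 12 together it was 0.28. KRT7 lost its call in 6 of the 9 fits without 1 library, after the GC correction, with DESeq2 size factors, library size only, robust=FALSE and limma-voom, which also ended KRT14 and KRT8. ITGB3 lost it in 7 of the 9 and with library size only, and HMOX1 in 2 and with no filter.

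Signalling genes moved in both directions. Of the immediate early genes 5 of 22 rose, 7 adjusted over the list alone (median 0.38, camera adjusted p = 0.000282, adjusted p = 0.206 with an estimated correlation). The phosphatase DUSP1 went from 80.2 ± 22.7 to 185.8 ± 56.7 CPM (log2 1.21 ± 0.25, edgeR adjusted p = 0.0177), and FOSB (0.95 ± 0.25), JUNB (0.42 ± 0.11) and KLF4 (0.40 ± 0.12) also rose. Of the NF-kB targets 5 of 25 rose, or 5 higher and 1 lower adjusted over the list alone (median 0.29, camera adjusted p = 0.0260, adjusted p = 0.206 with an estimated correlation). The prostaglandin synthase PTGS2 (1.20 ± 0.23), the cytokines IL6 (0.86 ± 0.22) and LIF (0.55 ± 0.14) and NFKB2 (0.45 ± 0.12) were the named members. The type I interferon list went the other way, with 5 of 35 genes lower and 1 higher, 6 and 2 adjusted over the list alone (median -0.20, camera adjusted p = 0.00329, adjusted p = 0.206 with an estimated correlation). IFI44 went from 53.9 ± 12.6 to 31.8 ± 2.90 CPM (log2 -0.76 ± 0.14, edgeR adjusted p = 0.00403), with falls of HERC5 (-0.68 ± 0.14), OASL (-0.60 ± 0.15) and DDX58 (-0.48 ± 0.12). Without tumours 15 and 12 together, 2 immediate early genes rose, 2 NF-kB targets rose and 1 fell, and 3 interferon genes fell in edgeR. No immediate early gene rose without tumour 9 alone or tumour 12 alone, 1 rose without tumour 6, and 3 without 7, 10, 11 or 15. The NF-kB count was 1 without tumours 9 or 10, 2 without 12 and 3 without 11 or 15. The count of lower interferon genes was 2 without tumour 9 and 3 without 1, 10 or 12. The NF-kB median was 0.19 without tumour 11 and 0.17 without tumours 15 and 12 together. After the GC correction 2 genes rose and 1 fell in the immediate early list, and the same in the NF-kB list, and FOSB, JUNB, KLF4, LIF and NFKB2 lost their calls. FOSB and KLF4 were also lost with limma-voom, KLF4 with library size only and DUSP1 with no filter.

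Antigen presentation, ERK output and FOXO targets did not pass as lists. For MHC class I presentation the camera adjusted p was 0.738, with HLA-E higher (0.45 ± 0.12) and the proteasome activator PSME2 lower (-0.41 ± 0.11) among 17 genes. TAP1 and TAP2 had edgeR adjusted p = 0.0570 and 0.0550. For ERK pathway output the camera adjusted p was 0.221, or 0.0355 and downward after the GC correction described below (adjusted p = 0.329 with an estimated correlation). Of its 23 genes MYC (0.47 ± 0.11) and LIF rose and DUSP6 (-0.61 ± 0.14) fell, with 4 higher and 6 lower adjusted over the list alone. The GC correction gave 1 higher and 7 lower, leaving out tumour 13 gave 3 and 6, leaving out tumour 12 gave 0 and 0, and the other fits without 1 library 1 to 3 higher and 0 to 2 lower. DUSP5 had edgeR adjusted p = 0.0532. The list of FOXO targets repressed by AKT had camera adjusted p = 0.397, and CITED2 (0.53 ± 0.12) and TXNIP (0.43 ± 0.11) rose among 23 genes. YPEL2 and ERBB3 had edgeR adjusted p = 0.0538 and 0.0544. Each of the 7 calls of genes in these 3 lists was lost in at least 1 fit that left out a library. Without tumour 13, 3 MHC class I genes rose and 1 fell, and 5 FOXO targets rose and 1 fell.

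Among metabolic genes, the cholesterol synthesis list rose with 4 of 26 genes higher and 1 lower, 6 and 1 adjusted over the list alone (median 0.10, camera adjusted p = 0.00330, adjusted p = 0.261 with an estimated correlation). The sterol reductase DHCR7 went from 25.7 ± 3.39 to 42.2 ± 4.42 CPM (log2 0.72 ± 0.12, edgeR adjusted p = 0.00329). INSIG1 (0.54 ± 0.12) and the transcription factor SREBF2 (0.69 ± 0.17) rose as well. Of these genes 2 rose in edgeR without tumours 15 and 12 together, and also 2 without tumour 12 alone. The median was 0.17 without tumour 11 and 0.16 after the GC correction, which ended the call of SREBF2, as did library size only. Oxidative phosphorylation did not pass (camera adjusted p = 0.125), with CYC1 (0.49 ± 0.12) higher and ATP5J (-0.51 ± 0.12) and ATP5F1 (-0.40 ± 0.12) lower among 41 genes, and COX6C at edgeR adjusted p = 0.0550. These 3 calls were lost without tumour 9 and without tumour 12, and those of CYC1 and ATP5F1 after the GC correction. That of CYC1 was also lost without tumours 1 or 11. ATP5F1 lost its call in every fit without 1 library except that without tumour 13, with limma-voom and with robust=FALSE. Without tumour 13, 2 genes of the list rose and 4 fell. The list passed, downward, without tumours 1, 6 or 7 with MSC (camera adjusted p = 0.0194, 0.0351 and 0.0346), but with an estimated correlation the adjusted p was 0.607, 0.663 and 0.694 there and 0.767 with all libraries. Cytosolic ribosomal protein genes did not pass with all libraries (camera adjusted p = 0.0664) and did, upward, without tumour 15 with MSC (1.09e-11). With an estimated correlation the adjusted p was 0.836 with all libraries and 0.246 without tumour 15. Of its 72 genes 1 rose in edgeR with all libraries, and 0 did adjusted over the list alone. The count was 23 without tumour 15, 7 without tumours 15 and 12 together, and 2 after the GC correction. It was 0 without tumours 1, 6, 7, 9, 10 or 12, 1 without tumour 11 and 2 without tumour 13. RPL10 and RPS2 had edgeR adjusted p = 0.0674 and 0.107.

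To relate the tumours to metastasis gene sets and to the CXCL12 and IGF signals that MSC can secrete, the fixed lists of these genes were compared. Of the bone metastasis genes 2 of 10 rose, DUSP1 and the protease ADAMTS1 (1.14 ± 0.30, edgeR adjusted p = 0.0450), and 5 did adjusted over the list alone (median 0.36, camera adjusted p = 0.00109, adjusted p = 0.206 with an estimated correlation). The count was 0 without tumour 9 and 1 without tumours 1, 6, 10, 11 or 12, and the call of ADAMTS1 was lost in 6 of the 9 such fits, with library size only and with no filter. After the GC correction 4 genes rose. MMP1 and IL11 had edgeR adjusted p = 0.0824 and 0.0952. The lung metastasis list did not move on balance (camera adjusted p = 0.823), with PTGS2 and LY6E (0.47 ± 0.14) higher and RARRES3 (-1.09 ± 0.17) and KYNU (-0.81 ± 0.18) lower among 17 genes. Leaving out 1 library ended the call of LY6E in 8 of the 9 fits, and it was lost with DESeq2 size factors, library size only, limma-voom, robust=FALSE and the GC correction too. KYNU lost its call without tumour 9 and without tumours 15 and 12 together. Without tumour 13, 4 genes of the list rose. In the CXCL12 and IGF axis 2 of 12 genes rose, also 2 adjusted over the list alone (median 0.22, camera adjusted p = 0.0260, adjusted p = 0.261 with an estimated correlation), and the list's call was lost without tumour 9 without MSC (0.114) and without tumour 10 with MSC (0.0707). The median was 0.14 without tumour 15 and 0.34 without tumour 13, and tumour 15 stood apart in the mean log2 CPM of the list (3.18 against at most 2.57). The higher genes were the IGF binding proteins IGFBP3, from 157.1 ± 27.2 to 255.5 ± 38.2 CPM (log2 0.70 ± 0.13, edgeR adjusted p = 0.00480), and IGFBP4 (0.60 ± 0.15), with 1 of them left without tumours 1, 6, 9 or 12, while IGFBP1 and IGFBP6 had edgeR adjusted p = 0.0990 and 0.122. The receptors showed no detectable difference, with log2 changes of -0.01 ± 0.14 for CXCR4 and 0.20 ± 0.21 for IGF1R (edgeR adjusted p = 0.970 and 0.591). CXCL12 and IGF1 were too low to test. CXCL12 had 47 counts in all with MSC, 34 of them in tumour 15, and 5 without. IGF1 had 20 counts with MSC, 14 of them in tumour 15, and 1 without. The pull-down took RNA of the tagged cancer cells, plus any carry-over, so these counts do not show how much of either MSC made.

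Markers of other cell types were examined because whole tumours were lysed. The fibroblast and MSC list was higher with MSC (2 of 17 genes in edgeR, 3 adjusted over the list alone, median 0.57, camera adjusted p = 0.000562, adjusted p = 0.360 with an estimated correlation). COL1A2 and the adhesion molecule MCAM (0.67 ± 0.13) passed, and COL5A1 and FBN1 had edgeR adjusted p = 0.0545 and 0.0953. Tumour 15 with MSC stood apart: COL3A1 was 21.2 CPM there and at most 1.55 in the others, and DCN 18.9 against at most 0.207. Without that tumour the list's median was 0.28 (camera adjusted p = 0.00880). Of the list's genes 1 rose without tumour 12 and 4 without tumour 13. The mean log2 CPM of this list was 0.889 ± 0.878 with MSC and 0.0862 ± 0.193 without (exact two-sided permutation p = 0.0317, 0.159 after Benjamini-Hochberg adjustment over 10 measures). This difference of 0.803 was 0.424 without tumour 15, the lowest value when 1 library was left out. Smooth muscle and pericyte markers gave -0.712 ± 0.410 and -1.28 ± 0.191 (exact permutation p = 0.0317, adjusted 0.159). Only 5 of the 12 genes of that list passed the filter. Its mean takes in genes near 0, such as DES at 0.332 CPM with MSC and 0.00380 without. DES was 0.817, 0.430 and 0.371 CPM in tumours 1, 6 and 15 with MSC and at most 0.0403 CPM in the others, with or without MSC. The other marker lists gave exact permutation p = 0.127 (myeloid), 0.302 (skeletal muscle), 0.508 (endothelial), 0.667 (erythroid) and 0.937 (adipocyte). Tumours 1 and 6 with MSC had the highest mean log2 CPM of skeletal muscle markers (-1.05 and -0.571 against at most -1.96 elsewhere). ACTA1 was 4.19 and 9.54 CPM in them and at most 0.486 elsewhere, and MYH2 1.37 and 2.15 CPM against at most 0.304. As lists in camera, smooth muscle, myeloid, endothelial and skeletal muscle markers had adjusted p = 0.252, 0.823, 0.424 and 0.178, while 4 adipocyte and 0 erythroid genes were left to test. Single members passed in edgeR: TAGLN (1.76 ± 0.35) up and ACTG2 (-1.003 ± 0.27) down, CD68 (0.52 ± 0.15) up, and ESAM (0.59 ± 0.11) up with PECAM1 (-0.94 ± 0.19) down. CD68 (88.4 to 201.6 CPM) and ESAM (81.8 to 156.5 CPM) were abundant in every tumour. Other members of these lists differed widely. The myeloid gene ITGAM and the endothelial gene CDH5 were at most 0.131 and 0.143 CPM. LAPTM5 (31.8 to 56.3 CPM) and ROBO4 (26.9 to 45.2 CPM) were abundant in every tumour too. The leukocyte gene PTPRC was 3.58 CPM in tumour 1 with MSC and at most 0.54 elsewhere. With members this uneven, the rises of CD68 and ESAM do not by themselves show more myeloid or endothelial cells. CSPG4, RGS5, LAPTM5, LYZ, EMR1, TIE1 and EGFL7 did not pass, with edgeR adjusted p from 0.0667 to 0.637. The call of TAGLN was lost without tumours 9, 11 or 12, that of ACTG2 without 1, 9, 10, 11 or 15, and that of CD68 without 1, 6, 9, 10 or 12. Those of MCAM, ESAM and PECAM1 held when any 1 library was left out. TAGLN, ACTG2 and CD68 were also lost without tumours 15 and 12 together. TAGLN was highest in tumours 1 and 6 with MSC, at 56.98 and 37.84 CPM. It was 16.93 to 25.67 CPM in the other tumours with MSC, above every tumour without. Its call held when either tumour 1 or tumour 6 was left out. Whether RNA of muscle in these tumours adds to the rise of TAGLN was not tested.

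**Figure D3:**
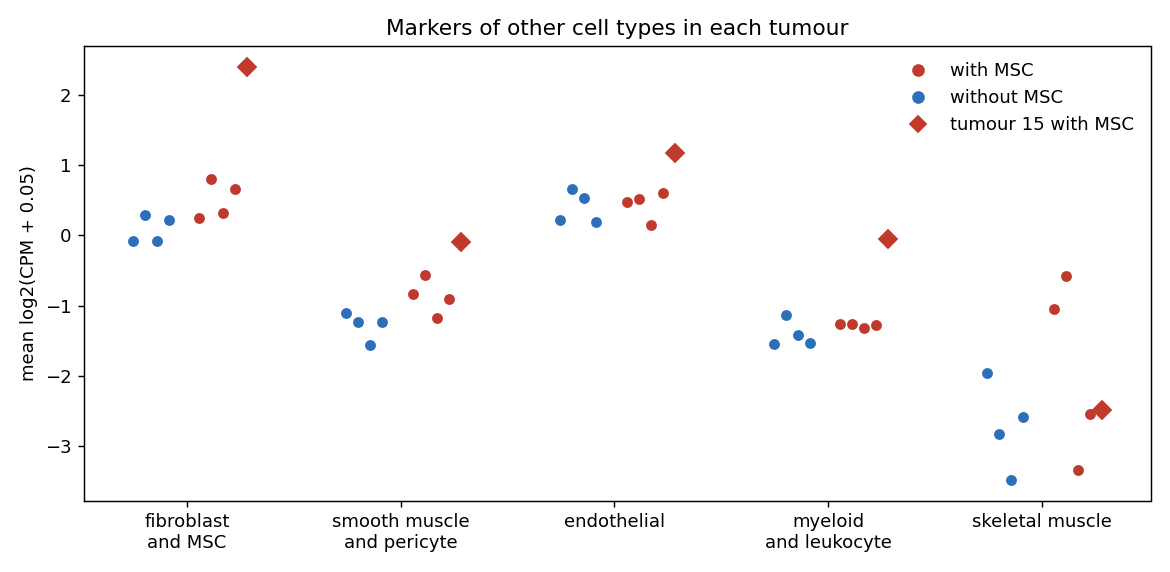
Mean log2(CPM + 0.05) of 5 lists of cell type markers in each tumour, without (blue) and with (red) MSC; each symbol is 1 tumour and the diamond is tumour 15 with MSC. For fibroblast and MSC markers tumour 15 is at 2.40 and the next highest tumour at 0.804.

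The share of counts in the most abundant genes and in ribosomal protein genes was compared as well. The 10 most abundant genes took 8.61 ± 0.728% of counts with MSC and 8.57 ± 0.498% without (exact permutation p = 0.921), and ribosomal protein genes 16.1 ± 2.02% and 14.9 ± 0.627% (exact permutation p = 0.317). Tumour 15 had 12.6% in ribosomal protein genes, and the other 4 tumours with MSC, at 16.4 to 17.5%, lay above those without, at 14.5 to 15.8%. Without tumour 15 the difference went from 1.18 to 2.06 percentage points (exact permutation, adjusted p = 0.143). RPL10A, the gene whose product carries the tag, took 0.228 ± 0.0284% and 0.195 ± 0.0129% (exact permutation p = 0.0635, adjusted 0.212). Tumour 15 had 0.179%, the other 4 tumours with MSC 0.230 to 0.247% and those without 0.176 to 0.204%. The gene had a log2 change of 0.24 ± 0.14 (edgeR adjusted p = 0.314). The smallest two-sided p that the splits of the 9 libraries allow is 0.0159. Adjusted over 10 measures, 1 measure alone at this limit cannot come under 0.05. Without tumour 15 fewer splits are possible and the limit is higher. The adjusted p of 0.143 for the ribosomal protein share there came with groups that did not overlap, so it cannot decide. Spearman correlations between libraries, across genes, were 0.988 to 0.994 within the tumours with MSC, 0.981 to 0.991 within those without, and 0.972 to 0.992 between groups. The first principal component (44.3% of variance) set tumour 12 without MSC at 98.6. On it the other tumours without MSC lay at -8.73 to 4.44 and those with MSC at -22.6 to -15.0.

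The called genes also differed in base composition. Genes higher with MSC had a median transcript GC content of 56.8%, lower genes 43.4% and genes not called 48.5%. Across genes, the correlation of a library's deviation with GC content ranged from -0.661 (tumour 9 without MSC) to 0.383 (tumour 6 with MSC), with means of 0.202 ± 0.149 with MSC and -0.179 ± 0.380 without (exact permutation p = 0.0794). Tumour 12 without MSC was at -0.249, and tumours 9 and 12 are those whose removal left the fewest calls. The labels name no batch, so whether these libraries were prepared apart from the others was not tested. After removing each library's trend with GC content and length, an alternative chosen after seeing the data, 471 genes were higher and 475 lower in edgeR, of which 367 and 301 were also called before. Of 95 named genes called, 77 kept their call after this correction and 34 kept it in every fit that left out 1 library.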

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

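Within each group, a tumour was singled out where its gap to the nearest other tumour, divided by the group's range, passed Dixon's 95% limit. This happened for 22 of 252 group values, and chance alone gives about 1 in 20. The count of genes highest in tumour 15 was chosen after the result was seen.

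Tumour 15 with MSC had the highest mean of fibroblast and MSC markers (gap ratio 0.744) and of myeloid and leukocyte markers (0.952). The myeloid mean takes in genes near 0, such as C1QC at 0.543 CPM there and at most 0.0202 elsewhere. CD68 was 131.5 CPM in tumour 15 and up to 201.6 elsewhere. It was lowest for the share of counts in ribosomal protein genes (0.766), the share in RPL10A (0.746), and the log2 CPM of RPL10A (0.771), RPL10 (0.731) and RPS2 (0.747), and highest for SLC7A5 (0.807). Tumour 12 without MSC was lowest for the RPL10A share (0.845), GCOM1 (0.947) and LIF (0.831), and highest for NME5 (0.842), SALL2 (0.839) and RARRES3 (0.874). Tumour 13 without MSC was highest for CRYAB (0.917), KRT14 (0.890) and AXL (0.928), and tumour 11 without MSC lowest for YPEL2 (0.831). With MSC, tumour 1 was highest for UCA1 (0.865), tumour 10 for LOX (0.735) and SLC2A1 (0.713), and tumour 7 lowest for OASL (0.818).

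RNA of other cells in the library of tumour 15 is a candidate source of the higher fibroblast and MSC markers with MSC, and stays open. That tumour was highest of the 9 for 15 of 17 tested genes, which restates that it stood apart for these markers and decides nothing. COL1A1 reached 55.4 CPM there against at most 26.1 elsewhere. As for the whole cause, without the tumour the list's median kept 0.484 of its value, between the bounds set beforehand, and the camera adjusted p was 0.00880. Tumour 15 also had the highest mean log2 CPM of adipocyte markers (-0.730 against at most -1.78) and endothelial markers (1.18 against at most 0.658). It was not highest for erythroid or skeletal muscle markers. Single genes were low, such as the adipocyte gene ADIPOQ at 1.17 CPM there and at most 0.215 elsewhere. MSC left in the tumour, mouse cells and a response of the cancer cells cannot be told apart, because the tables do not separate species or cells.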

How the results depend on the processing

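The GC correction and the fit without tumours 15 and 12 together were chosen after seeing the data. Genes higher and lower with MSC stayed within 1.5 times 563 and 484 under other scalings, no filter, the stricter filter, robust=FALSE, thinning and the GC correction. DESeq2 called 856 and 790, an adjusted p under 0.10 gave 956 and 888, limma-voom called 289 lower, and 201 and 101 were called without tumours 15 and 12. Leaving out 1 library gave 151 to 985 higher and 94 to 863 lower. The causes were not tested.

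Of 28 lists, 16 passed in camera, 15 to 17 when 1 library was left out, 18 after the GC correction, and 0 with an estimated correlation. With that estimate the adjusted p was 0.206 for mitosis, hypoxia, ER chaperones, TGF-beta, ATF4, immediate early, NF-kB, interferon and bone metastasis genes, 0.244 for S phase and mesenchymal genes, 0.261 for epithelial, cholesterol and CXCL12 and IGF genes, 0.335 for integrins and 0.360 for fibroblast markers. By fry, fibroblast markers gave 0.124 and smooth muscle markers 0.0466. Ribosomal protein genes passed with library size only (0.0198), the stricter filter (0.0308), the GC correction (0.000192) and without both tumours (1.48e-12), but not with an estimated correlation (0.836, or 0.582 after the GC correction). They ranged from 1.09e-11 to 0.603 when 1 library was left out. ERK output passed after the GC correction (0.0355, or 0.329 with an estimated correlation). Leaving out 1 library gave 0.0194 to 0.679 for oxidative phosphorylation and 0.00802 to 0.114 for the CXCL12 and IGF axis. The cause was not tested.

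No named gene changed direction with its call. Of 95 called, 33 kept it under every alternative set before the data were examined and 48 without tumours 15 and 12. Thinning the other libraries to the smallest gave 540 and 506.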

Other observations

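Further gene groups were put together after the called genes had been seen, so their tests describe these data and are no independent evidence. Adjustment was over these 4 lists, not the 26 fixed ones. Before adjustment, camera with an estimated correlation gave p = 0.0130 for collagen processing and 0.0175 for the fixed ER chaperones, which did not pass. The collagen processing list shares called genes, such as P4HA2 and LOX, with the fixed hypoxia list. Genes of collagen processing and crosslinking were higher with MSC: 14 of 29 rose and none fell in edgeR (median 0.50, camera adjusted p = 2.98e-13, adjusted p = 0.0379 with an estimated correlation, over 4 lists). They included the lysyl hydroxylase PLOD2 (log2 0.88 ± 0.13), the prolyl hydroxylase P4HA1 (0.85 ± 0.19), the collagen chaperone SERPINH1 (0.84 ± 0.22) and the protease BMP1 (0.64 ± 0.15). Of the genes of fatty acid synthesis and desaturation 8 of 25 rose, with the desaturases FADS3 (1.18 ± 0.14), FADS2 (0.62 ± 0.12) and SCD (0.72 ± 0.11) and the regulator SREBF1 (0.82 ± 0.17) among them (camera adjusted p = 1.75e-05, adjusted p = 0.0379 with an estimated correlation). Without tumours 15 and 12 together, 6 and 5 genes of these lists rose in edgeR. The collagen count was 8, 6 and 5 without tumours 10, 9 and 12, and the fatty acid count 5 without tumour 12. Of fibroblast and MSC markers, a list that also holds collagens, 2 of 17 rose (median 0.57, or 0.28 without tumour 15; adjusted p = 0.360 with an estimated correlation and 0.124 by fry). RNA of other cells therefore stays open for the collagen processing genes, of which 14 were called higher without tumour 15 (median 0.52), not compared gene by gene with those called before.

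Lysosomal hydrolases were higher, with 11 of 42 genes up, such as the cathepsins CTSC (0.50 ± 0.12) and CTSZ (0.50 ± 0.12) (camera adjusted p = 1.16e-07, adjusted p = 0.150 with an estimated correlation). Splicing factors were lower, with 17 of 62 down and 1 up (median -0.27, camera adjusted p = 1.15e-10, adjusted p = 0.150 with an estimated correlation). RBM25 (-0.59 ± 0.13), LSM5 (-0.59 ± 0.13) and SRSF11 (-0.55 ± 0.11) fell, and SF3A2 (0.76 ± 0.14) rose. Without tumours 15 and 12 together, 3 hydrolases rose, and 2 splicing factors fell and 1 rose in edgeR. The hydrolase count was 0 without tumour 9 or tumour 12, 2 without 6, 3 without 1 or 10, 6 without 7, 11 or 15, and 18 without 13. Of splicing factors 1 fell without tumour 12, 3 without 1, 9 or 10, 5 without 11, 9 without 15, 10 without 7 and 31 without 13.

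Chance is an unlikely source of the calls: 1 of 100 splits of the 9 libraries into 5 and 4, the real one, called as many as 1047 genes, and the highest other called 48.

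Genes whose protein has a hydrophobic stretch, a mark of secreted and membrane proteins, were frequent among the higher genes: 65.7% of higher genes had one, 15.7% of lower genes and 34.7% of genes not called. The median log2 change was 0.12 with a stretch and -0.04 without. Per library, the median deviation in log2 CPM of these genes minus that of other genes was 0.0820 ± 0.0735 with MSC and -0.0889 ± 0.0929 without, with overlap between the groups (exact permutation p = 0.0317, a test chosen after seeing the data). The difference kept 0.846 of its value after correction, which argues against the fitted trend with GC content and length as the whole cause. How much of a real bias the correction removes is not known, so a bias that it left in place stays open. For 1 aberrant library the lowest value was 0.789, without tumour 9 without MSC, just short of the bound of 0.8, so a part stays open. Among genes not called the difference was 0.773 of that over all genes, which different recovery of membrane-bound polysomes between tumours and a class-wide response to MSC would both give, so both stay open.

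The lower mitosis genes with MSC kept 0.832 of their median after the GC and length correction. This argues against the fitted trend as the whole cause, while a bias that the correction left in place stays open. When 1 library was left out, the median nearest 0 kept 0.798 of its value, without tumour 12 without MSC, so a contribution of that library stays open. That cancer cells near MSC divide more slowly is a hypothesis that no table here tests, and a different mix of cells in the tumours was not tested either.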
